A study of Mus musculus with 5 samples.

How the data were processed

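RNA of 5 cultures of B16F1 mouse melanoma cells was measured on 5 Agilent arrays with 1 dye (Cy3), 1 array per culture. The arrays fell into 4 groups: wild-type cells with vehicle (n = 1), with TGF-β1 (n = 1), with TGF-β1 and CCG1423 (n = 1), and Tmsb4x knockout cells with TGF-β1 (n = 2 clones). The groups were taken from the sample labels (for the CCG1423 array from its title and description, since its treatment field names CCG1423 alone), and the replicate number of the knockout is its clone number. Per the labels, cRNA was made from total RNA with a low-input labelling kit. The labels do not say whether cultures were grown on separate occasions, so p-values measure only the spread between these samples. The file headers place all 5 arrays on the same slide in the same scan, so no batch could be tested.

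Each array came with its scanner output, made with Agilent Feature Extraction 12.0.3.1 per the labels and the file headers. The intensity used here, the processed signal, was background-subtracted and spatially detrended within each array per the file headers, and was not normalized between arrays. The 0 or 1 flags for outlier spots, saturation and signal well above background were also set by that software, per the file headers. The deposited value table of the series holds the same intensity multiplied by a constant for each array, which was found by setting each column against its array. The log2 of that constant was -0.01 for vehicle, 0.12 for TGF-β1, 0.34 for CCG1423, -0.17 for clone 1 and -0.08 for clone 2. Its column medians were 26.9, 29.2, 27.5, 23.2 and 28.8 in the same order. The values are linear, not centred, and run in the direction of the intensity; the rule behind the constants stays unknown.

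Control spots (3671 per array) and spots flagged as outliers (107 to 141 per array) were left out of 59305 other spots. The log2 processed signal was averaged over the spots of a probe, and the 75th percentile over probes was subtracted on each array. A further 10 probes with all spots flagged on an array were dropped, which left 56595. The files give accessions but no gene names, so probes were named by matching the RefSeq accession, without version, to a RefSeq gene table of assembly GRCm38.p6. This named 32988 probes for 22907 genes and left 23607 probes unnamed; the headers name an older mouse build, so no coordinates are given. For the 7897 genes with several probes, the probe with the highest mean over the 5 arrays stood for the gene.

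A gene entered a comparison when its probe was well above background on every array of at least 1 of the groups compared. Where the other side was not well above background, folds and fold counts used a floored level. That was the higher of its own signal and the lowest signal among probes well above background on that array. Such a fold is a bound, written "at least". It is taken on normalized log2 values. Log2 differences, list medians, limma and camera used the signal without this floor, also where it was below background. Comparisons of single arrays were not tested in the main analysis: genes were counted at 2-fold or more, and the same count between the 2 knockout clones is given as the spread within a group. The knockout was tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a mean-variance trend) on all 5 arrays in 4 groups, with Benjamini-Hochberg adjustment and a threshold of 0.05. The spread came from the 2 clones alone (1 residual degree of freedom), and the single wild-type array was assumed to vary like them. An adjusted p in the text is from that fit. The remaining steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

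The text draws on Tmsb4x and a set of genes of the actin, MRTF and TGF-β pathways in any case. Per comparison it also draws on the 10 genes most higher and the 10 most lower among those measured on all arrays compared with a mean level above the median of genes kept. Up to 2 highest and 2 lowest members of each of 23 gene lists at 2-fold or more complete the rule. Interferon genes beyond the rule, genes in overlaps, limma calls and list members bright on 1 array were picked as examples after their values were seen. The lists, the rule and the alternatives were fixed before the data were examined, except 2 alternatives added afterwards: all probes, named or not, and only genes well above background on every array compared. For a list, the median log2 difference is given with its percentile among 10000 random lists of equal size matched on mean expression, which describes these arrays and is not a p-value. For the knockout, lists were also tested with limma's camera at a preset correlation of 0.01 and with an estimated correlation. Lists with under 3 measured members were not summarised; this left out endothelial markers everywhere.

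The comparisons share the wild-type TGF-β1 array. Overlaps between them are therefore given beside the mean of 100 simulations of unchanged arrays, drawn from the difference between the clones at like brightness, and beside the overlap of independent lists. The clone difference includes any biology that differs between clones, so the simulated noise can be too large. On simulated data for the knockout fit over 13729 genes, 0% of 200 genes changed 2-fold and 0% of those changed 4-fold were recovered at adjusted p 0.05, against 89.5% at 16-fold, where 17 of 196 calls were false. At an unadjusted p of 0.05, 68.5% of the 2-fold genes were recovered. The code for fold counts, tested on simulated data of 12058 genes, recovered 100 of 100 planted genes with 0 false calls.

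Alternatives were quantile normalization, normexp background correction (offset 50) with quantile normalization, median scaling and the deposited value table. Others were no filter on dim probes, only genes well above background on all 5 arrays, the mean of all probes of a gene, thresholds of 1.5-fold and 3-fold, other limma settings, and leaving out each clone. The mean spot signal is not among the columns used here, so normexp used the median spot signal with the median local background. The number of arrays limits the precision throughout.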

Results

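The series set out to relate thymosin β4, an actin monomer-binding peptide encoded by Tmsb4x, to TGF-β and MRTF signalling in B16F1 cells, a mouse melanoma line. MRTFs are coactivators of the transcription factor SRF that monomeric actin holds inactive, and CCG1423 is a small-molecule inhibitor of that pathway. Wild-type cells received vehicle, TGF-β1, or TGF-β1 with CCG1423, and 2 Tmsb4x knockout clones received TGF-β1. TGF-β1 was given at 10 ng/ml and CCG1423 at 10 µM, for 2 days. The series title and the sample labels speak of a knockout, the design text of a knockdown. For the CCG1423 array the title and description name both agents and the treatment field only CCG1423; it was taken as both, and Tnnt2 and Ccn2 were 46.5-fold and 25.2-fold higher there than with vehicle. Each condition in wild-type cells had 1 array, so differences among these have no replicate check. Between 48.2% and 53.8% of probes were well above background on each array, and 0 spots were saturated. The 75th percentile of the signal was 299 with vehicle, 294 with TGF-β1, 230 with CCG1423, and 281 and 329 in the clones. The lowest signal called well above background was 26.0 on the clone 2 array and 13.3 to 15.5 on the others, so clone 2 gave weaker bounds for dim genes.

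Tmsb4x was measured well above background on all 5 arrays. Its normalized log2 level was 5.05 with vehicle, 7.12 with TGF-β1, 6.79 with TGF-β1 and CCG1423, 5.44 in clone 1 and 4.28 in clone 2. The clones thus lay 3.21-fold and 7.16-fold below wild-type cells under TGF-β1 (log2 difference -2.26, SE 0.44, adjusted p = 0.0857), which did not pass the threshold. Clone 1 lay above the vehicle level and clone 2 below it. The labels do not say which part of the gene was edited, and a probe outside that part would not report the loss of the protein. Tmsb10, the related β-thymosin, differed from wild type by 0.05 in clone 1 and -0.21 in clone 2 on the log2 scale.

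**Figure D1:**
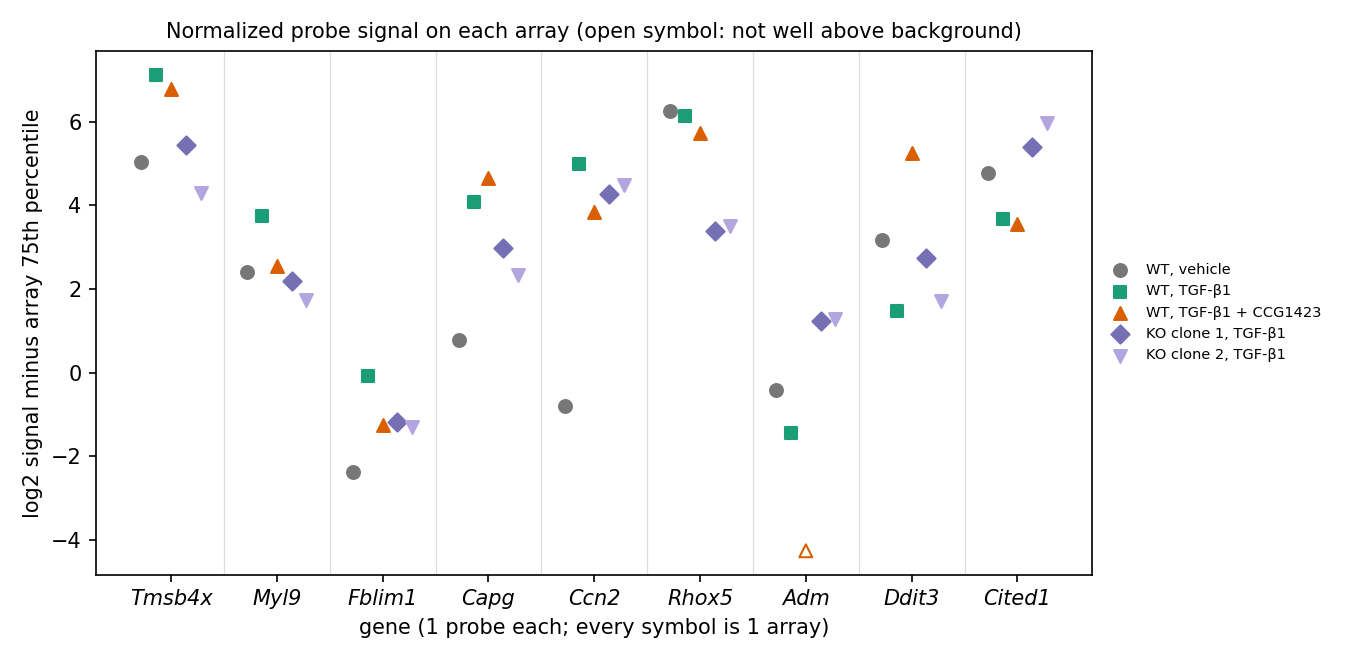
Normalized probe signal (vertical axis, log2 signal minus the 75th percentile of its array) of 9 genes (horizontal axis), with a symbol for each of the 5 arrays. Tmsb4x runs from 4.28 in clone 2 to 7.12 in wild-type cells with TGF-β1, Rhox5 is lower in both clones than on the 3 wild-type arrays, and the open symbol marks Adm with CCG1423, which was not well above background.

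The first comparison asks what TGF-β1 does to wild-type cells. Among the genes highest with TGF-β1, Tnnt2, cardiac troponin T, was 86.6-fold higher and Ccn2, a matricellular growth factor, 55.5-fold. Lims2, a focal adhesion adaptor, was 39.8-fold higher, Col1a1, a chain of type I collagen, 29.7-fold, and Pmepa1, a feedback inhibitor of TGF-β signalling, 16.5-fold. Tmsb4x itself was 4.21-fold higher. On the lower side stood Tyr, the tyrosinase that starts melanin synthesis (3.28-fold), Oca2, a melanosomal transport protein (4.50-fold), Gsta2, a glutathione transferase (4.28-fold), and the stress-response factor Ddit3 (3.23-fold).

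TGF-β and SMAD targets had a median log2 difference of 0.81, above all matched random lists, with 8 of 20 measured members at least 2-fold higher and 0 lower. Smad7, the inhibitory SMAD, was higher by 2.58 on the log2 scale, and Tgif1, a SMAD corepressor, was 3.08-fold higher. MRTF-SRF cytoskeletal targets had a median of 0.41 at percentile 100, with 9 of 33 members higher and 1 lower. Fblim1, a filamin-binding adaptor, was 4.90-fold higher, Cald1, the actin-binding caldesmon, 4.02-fold, and Myl9, a myosin regulatory light chain, 2.52-fold. Other members of that list differed little: Acta2 by 0.29, Tagln by 0.27, Vcl by -0.12 and Srf by -0.11 on the log2 scale, and Cnn1 was not well above background on any array. YAP-TEAD targets had a median of 0.56 at percentile 100, with 5 of 20 members higher; beside Ccn2 these included Gadd45b (2.79-fold) and Ccn1 (2.35-fold). Mrtfa and Mrtfb differed by 0.57 and 0.90.

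Interferon response genes were higher with TGF-β1 too, with a median of 0.76 at percentile 100 and 10 of 28 members at least 2-fold higher. Between the 2 clones, which shared a treatment, this list differed more, by a median of 2.57. Oasl2, an interferon-induced oligoadenylate synthetase-like protein, was 6.38-fold higher and Cxcl10, an interferon-induced chemokine, 5.48-fold. NF-κB inflammatory genes had a median of 0.38 (percentile 99.9), led by the cytokine Il6, which was at least 14.2-fold higher and not well above background with vehicle. Matrix proteases and inhibitors had a median of 0.39 (percentile 99.99), with Serpine2, a protease inhibitor, 5.41-fold higher and Mmp14 at 0.25 on the log2 scale; Mmp9 was not well above background on any array. Extracellular matrix genes had a median of 0.17 (percentile 99.8), with 9 of 33 members higher and 3 lower; Fn1, fibronectin, was 2.29-fold higher.

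Melanocyte pigmentation genes had a median of -0.19 (percentile 0.03), with 5 of 27 members at least 2-fold lower and 0 higher. Genes of the integrated stress and unfolded protein responses (median -0.27), NRF2 targets (-0.39) and p53 targets (-0.34) lay below all 10000 random lists. Slc7a11, the cystine transporter, was 3.62-fold lower, Gstm1, a glutathione transferase, 2.36-fold, and Plk2, a p53 target, 2.09-fold. The hypoxia and glycolysis list stood at -0.17 (percentile 0.68), EMT and adhesion genes at 0.12 (98.9) and housekeeping genes at -0.18 (1.30). Immediate-early genes had a median of 0.01 (percentile 73.5), actin turnover genes 0.03 (95.7), cell cycle genes -0.09 (16.6), heat shock genes -0.04 (61.0) and cholesterol synthesis genes -0.07 (34.1). Markers of other cell types gave -0.03 for immune cells (6 measured), -0.42 for fibroblasts (3) and -0.38 for epithelium (5).

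In all, 1162 of 14145 genes differed at least 2-fold between TGF-β1 and vehicle, 700 higher and 462 lower. On both arrays 413 of the higher and 209 of the lower genes were well above background, and the others are bounds. The 2 knockout clones, which shared a treatment, differed at least 2-fold in 1049 of 13849 genes (7.57%, against 8.21% here), so the count hardly exceeds the difference between the clones. On the 12058 genes measured on all arrays it was 511, below the mean of 560 in simulations of unchanged arrays. Both yardsticks include any biology that differs between the clones and can be too large. They cannot show that the TGF-β1 differences are noise. Several list members at the lower end were above background on the vehicle array alone by the probe used (Jup, Lum, Tnc, Plau, Mmp16, Birc3 and Il1a).

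The next comparison sets CCG1423 with TGF-β1 against TGF-β1 alone in wild-type cells. Angptl6, a secreted angiopoietin-like protein, was 15.5-fold higher with the inhibitor. Ddit3, which encodes the stress-induced factor CHOP, was 13.7-fold higher, Gadd45a, a growth-arrest and DNA-damage gene, 10.3-fold, Nupr1, a stress-induced nuclear protein, 10.2-fold, and Slc7a11 6.54-fold. Cd164, a sialomucin, was 26.2-fold lower, Irgm1 and Rtp4, both interferon-inducible, 6.66-fold and 5.25-fold lower, and Smtnl2, a smoothelin-like protein, 4.86-fold lower.

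All 19 measured genes of cholesterol synthesis lay below 0, with a median of -1.08 and 13 at least 2-fold lower; Insig1, a sterol sensor partner, was 3.45-fold lower and Nsdhl, a sterol dehydrogenase, 2.96-fold. All 29 cell cycle genes also lay below 0, with a median of -0.89 and 11 at least 2-fold lower, among them Rrm2, a ribonucleotide reductase subunit (3.19-fold), and Cdc6, a replication licensing factor (3.08-fold). Interferon response genes (median -0.91, 11 of 28 lower) and hypoxia and glycolysis genes (-0.76, 6 of 24 lower) lay below all random lists as well; the interferon difference is smaller than that between the clones. Oasl2 was 7.33-fold lower, Ifit1 3.69-fold and Egln3, an oxygen-sensing hydroxylase, 4.22-fold. The p53 list had a median of 0.60 with 17 of 18 members above 0, and the stress response list 0.39 with 9 of 24 members higher and 2 lower, both at percentile 100. Calr and Sdf2l1, endoplasmic reticulum proteins on the latter list, were 2.39-fold and 2.61-fold lower.

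MRTF-SRF targets had a median of -0.25 and a mean of -0.09 with CCG1423, at percentile 3.14, with 3 of 33 members at least 2-fold lower and 1 higher. By sign, 21 members lay below 0 and 12 above. Myl9 and Fblim1 were 2.27-fold and 2.26-fold lower, and Acta2 differed by -0.66 and Tagln by 0.04 on the log2 scale. Ccn2 was 2.20-fold lower and Ccn1 2.15-fold higher. TGF-β and SMAD targets had a median of -0.14 and a mean of 0.14 (percentile 33.6), with Smad7 at -0.46 and Tgif1 2.27-fold higher. Fn1 was 2.05-fold higher, Timp3, a metalloproteinase inhibitor, 4.66-fold higher, and Axl, a receptor tyrosine kinase, 4.20-fold higher, whereas Col1a1 was 2.51-fold lower. Tmsb4x differed by -0.34, and Tgfb1 was, by the probe used, well above background on the CCG1423 array alone (at least 2.45-fold higher). Its other probe gave -0.45 and was not well above background on any array, so this rests on 1 dim probe. Melanocyte genes had a median of -0.23 (percentile 7.51), with 7 of 27 members at least 2-fold lower, among them Mlana, a melanosomal antigen (3.14-fold).

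Actin turnover genes stood at 0.14 (percentile 97.5), EMT and adhesion genes at 0.20 (97.3), proteases at -0.26 (4.88), heat shock genes at -0.42 (2.97), immediate-early genes at -0.29 (9.24) and matrix genes at -0.05 (48.6). YAP-TEAD targets (-0.09), NRF2 targets (median -0.00, mean 0.24), NF-κB genes (-0.12) and housekeeping genes (-0.05) had percentiles between 34 and 66. Immune markers had a median of 0.14 and epithelial markers -0.48. In all 1826 of 14057 genes differed at least 2-fold, 845 higher and 981 lower, of which 549 and 721 were measured on both arrays. Among 12058 genes measured on all arrays, 1139 differed, against a mean of 562 and a maximum of 610 in simulations with the spread of the clones. Probes of a gene did not always move together: of 677 genes with several measured probes and at least 1 at 2-fold, all probes passed in 189, and for Sfpq, a splicing factor, the 3 probes gave -3.48, -1.31 and -0.05.

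**Figure D2:**
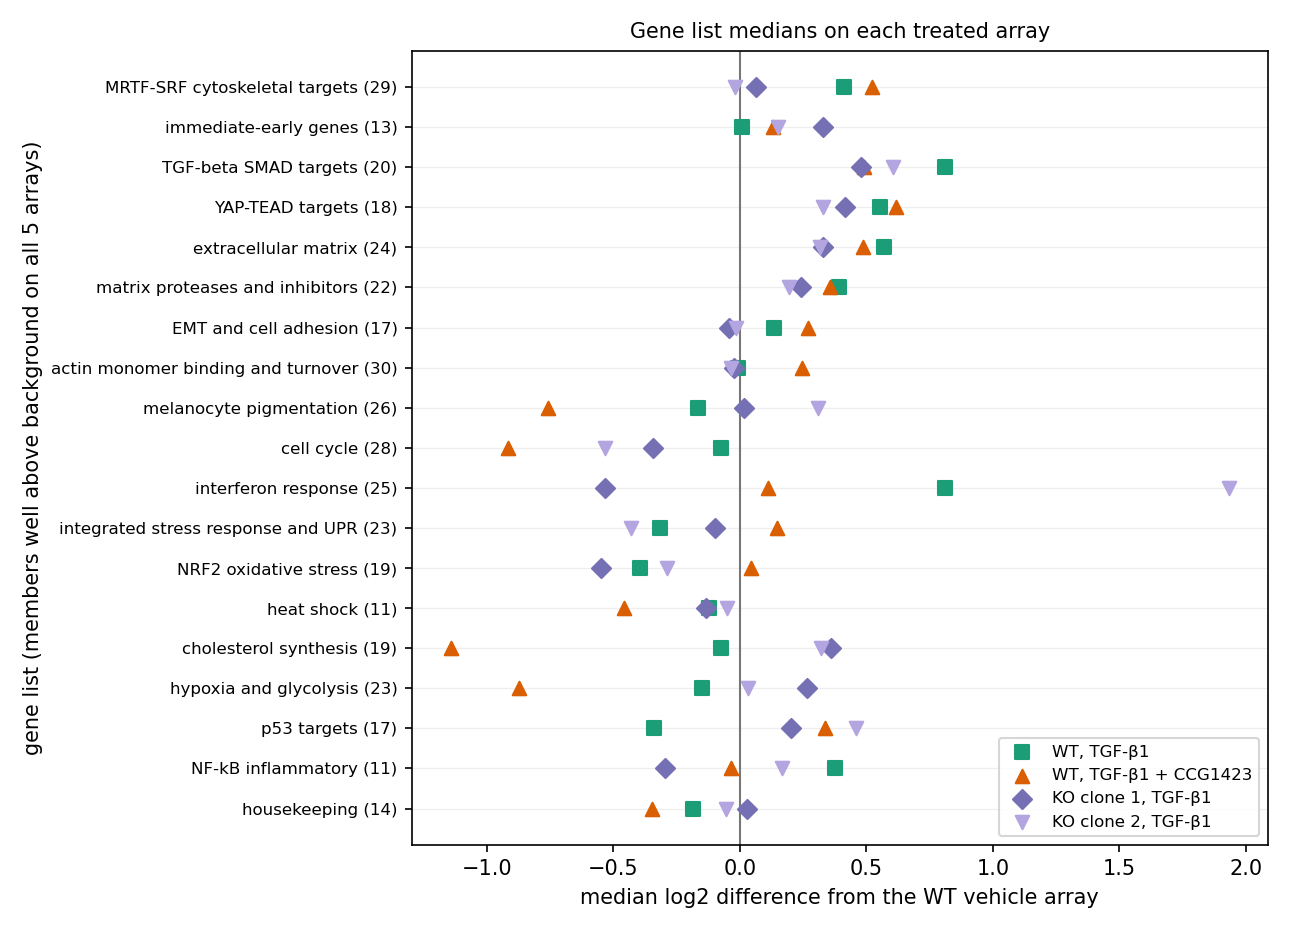
Median log2 difference from the wild-type vehicle array (horizontal axis) for 19 gene lists (vertical axis, members well above background on all 5 arrays in brackets), with a symbol for each of the other 4 arrays. The MRTF-SRF list lies at 0.41 with TGF-β1 and 0.52 with CCG1423 added, and at 0.06 and -0.02 in the clones, while the interferon list spans -0.53 in clone 1 to 1.93 in clone 2. Medians against vehicle cannot be subtracted. Set directly against TGF-β1 alone, 21 of 33 MRTF-SRF members were below 0 with CCG1423 (median -0.25).

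The third comparison asks how Tmsb4x knockout clones differ from wild-type cells when both receive TGF-β1. Rhox5, an X-linked homeobox gene, fell in both clones, with a log2 difference of -2.68 (SE 0.29, adjusted p = 0.0176; -2.74 in clone 1 and -2.62 in clone 2). Adm, which encodes the hypoxia-responsive peptide adrenomedullin, rose by 2.71 (SE 0.35, adjusted p = 0.0307; 2.68 and 2.74). Myl9 lay 2.90-fold and 3.97-fold below wild type, Capg, an actin filament-capping protein, 2.15-fold and 3.37-fold, Col4a1, a basement membrane collagen chain, 2.72-fold and 2.63-fold, and S100a4, a calcium-binding protein linked to metastasis, 4.39-fold and 24.3-fold. These 4 did not pass (adjusted p from 0.0588 for Myl9 to 0.173 for Capg). Cited1, a transcriptional coregulator of melanocytes, was 3.28-fold and 4.87-fold higher and Aldoc, a glycolytic aldolase, 6.10-fold and 3.50-fold, both at adjusted p = 0.0509.

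MRTF-SRF targets were lower as a group, with a median of -0.42 in clone 1 and -0.50 in clone 2 and 28 of 32 members below 0. None of the 32 passed over all genes; adjusted over the list alone, 1 member passed on the higher side and 1 on the lower. With camera the list was lower at the preset correlation (adjusted p = 4.07e-07), and the call was lost with an estimated correlation (adjusted p = 0.557). At least 2-fold lower in both clones were Myl9, Fblim1 (2.13-fold and 2.32-fold) and Mical2, an actin-oxidizing enzyme (2.75-fold and at least 3.98-fold). Fhl1, a LIM-domain protein on the same list, stood 3.45 and 2.66 higher on the log2 scale (adjusted p = 0.0588). Acta2 differed by -0.59 and -0.50, Tagln by -0.33 and -0.92, Vcl by -0.61 in each clone, and Srf by -0.40 and -0.46. Mrtfa differed by -0.41 and -0.47 and Mrtfb by -0.36 and -0.14.

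The TGF-β and SMAD targets differed less, with a median of -0.14 (percentile 1.45); Smad7 stood at -0.40 and -0.50 and Id3, a helix-loop-helix inhibitor, at -1.23 and -1.24. Ccn2 differed by -0.73 and -0.50, and the YAP-TEAD list had a median of -0.15 (percentile 3.87). Matrix genes had a median of -0.30 (percentile 0.01) and proteases -0.36 (percentile 0): Lamb1, a laminin chain, was 2.15-fold and 2.88-fold lower and Mmp15, a membrane-bound metalloproteinase, 2.39-fold and 2.58-fold, whereas Col1a2 was 3.29-fold and 2.80-fold higher. Fn1 differed by -0.62 and -0.77 and Mmp14 by -0.20 and -0.53. Il6 was 3.32-fold and 3.11-fold lower (adjusted p = 0.281), and the NF-κB list had a median of -0.22. Adjusted over the list alone, 3 matrix genes passed on the lower side and 1 on the higher, 2 NF-κB genes passed on the lower side, and 2 actin turnover genes did, in a list with a median of -0.10. The SMAD, YAP-TEAD and protease lists had 1 such gene each, on the lower side. The protease gene, Mmp23, and the NF-κB gene Icam1 were well above background on the wild-type TGF-β1 array alone. These passes were not adjusted over the number of lists.

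Hypoxia and glycolysis genes were higher, with a median of 0.41 and 22 of 24 members above 0; besides Adm, which passed over all genes, Aldoc led the list. Cholesterol synthesis genes (0.41, 17 of 19 above 0), p53 targets (0.37, 17 of 17) and melanocyte genes (0.28, 19 of 27) were also above 99.9% of random lists. Trp53inp1, a p53-induced regulator, was 2.10-fold and 3.60-fold higher, and Tspan10, a pigment-cell tetraspanin, 2.32-fold and 3.48-fold. Adjusted over the list alone, 2 hypoxia genes and 2 melanocyte genes passed on the higher side, and 0 genes of the cholesterol, p53 and cell cycle lists did. Cell cycle genes had a median of -0.36 with 27 of 29 members below 0 and no member at 2-fold in both clones. With camera at the preset correlation, the hypoxia, cholesterol, p53, melanocyte, cell cycle, protease, matrix, YAP-TEAD and NF-κB lists also passed (adjusted p from 4.07e-07 to 0.0097), and with an estimated correlation each lost the call (adjusted p = 0.557).

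The interferon list went opposite ways, with a median of -1.54 in clone 1 and 1.09 in clone 2. Usp18, an interferon-induced protease, lay at -3.82 and 1.76, Irf7, an interferon regulatory factor, at -2.40 and 1.60, and Ifit1 at -2.13 and 1.34. Smaller medians were found for immediate-early genes (0.07), EMT and adhesion genes (-0.20), stress response genes (0.08), NRF2 targets (-0.02), heat shock genes (-0.06) and housekeeping genes (0.06). Immune markers stood at 0.18 and epithelial markers at -0.26, and fibroblast markers had under 3 measured members.

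In limma 32 of 13729 genes passed adjusted p 0.05, 1 higher and 31 lower, against 793 at an unadjusted p under 0.05. A share of 0.05 of unchanged genes would pass the unadjusted threshold, so most of the 793 could arise by chance. Of the 32, 4 were well above background on all 3 arrays compared (Rhox5, Adm, Aadacl4 and Gm5640), and 26 were bright with TGF-β1 in wild-type cells and below background in both clones, such as Cpa1, a pancreatic carboxypeptidase (at least 28.8-fold). Most of these 26, Cpa1 among them, were also at least 2-fold higher with TGF-β1 than with vehicle and lower with CCG1423. For them, a high signal on the single wild-type TGF-β1 array and a loss in the clones could not be told apart. By size, 313 genes were at least 2-fold different the same way in both clones, 96 higher and 217 lower, of which 79 and 53 were measured on all 3 arrays. Of the 12058 genes measured on all 5 arrays 100 were, against a mean of 185 in simulations of unchanged arrays. The number of calls rests on the processing: quantile normalization and averaging of probes left 0, and the values of the deposited table gave 220. Those values shift the median of all genes by -0.20 in this comparison, -0.13 for CCG1423 and 0.10 for TGF-β1, so differences from them are relative to that shift.

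The last comparison asks which genes higher with TGF-β1 were lower with CCG1423 or in the clones. Among genes measured on all 5 arrays, 376 were at least 2-fold higher with TGF-β1; 129 of these were at least 2-fold lower with CCG1423 and 20 in both clones. Myl9, Fblim1, Map2, a microtubule-associated protein, and Plxna2, a semaphorin receptor, were among 13 genes lower in both settings. Tmsb4x, Capg, Col4a1 and Lamb1 were lower in both clones and not at 2-fold with CCG1423. For Lamb1 this depends on the probe. Of its other probes, 1 gave -1.04 with CCG1423 and -0.62 and -1.11 in the clones on the log2 scale, and 1 gave 0.10, -1.09 and -1.65. Another 14 of the 376 were higher still with CCG1423, among them Ccn1, Fn1, Timp3, Tgif1 and the cytokine Il11; independent lists would share 14.1, and simulated unchanged arrays shared 2.68. Pmepa1 kept within 2-fold of its TGF-β1 level with CCG1423 and in each clone.

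Counting bounds, 360 of 700 genes (51.4%) higher with TGF-β1 were lower with CCG1423 (343) or in both clones (167). The wild-type TGF-β1 array enters every side of this comparison, so a chance high value there lowers all others against it. On the 12058 genes measured everywhere, independent lists would share 21.4 genes for CCG1423 and 1.40 for the clones, while simulated unchanged arrays shared 94.5 (at most 117) and 68.5 (at most 85). The covariance of TGF-β1 against vehicle with CCG1423 against TGF-β1 was -0.06, against -0.13 in the simulation. That of TGF-β1 against vehicle with the clone mean against TGF-β1 was -0.03, against -0.13. With a single TGF-β1 array in wild-type cells the shared array could not be split. For the clones, the 20 genes observed lay below the simulated mean, so the shared array alone could account for their excess over independent lists. For CCG1423, the 129 observed lay above the highest simulation, and part of the excess may come from that array.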

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

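The tests of the interferon list and of genes bright on 1 array were chosen after the result was seen, as was the comparison of the MRTF-SRF list with vehicle; the other 2 tests of that list were written before.

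The interferon response list drew attention because the clones, set against the same wild-type array, went opposite ways: its median log2 difference was -1.54 in clone 1 and 1.09 in clone 2, and this difference was not tested. Of 29 members, 25 were higher in clone 2 than in clone 1, and H2-K1, a class I histocompatibility gene, ran the other way (-4.83). A brightness or background difference between the clone arrays is argued against, since the list median between clones exceeded the highest matched random list by 2.20. A large amount of immune cell RNA in the clone 2 culture is argued against too: Ptprc, Adgre1, Lyz2 and Laptm5 were not well above background in clone 2. The measured immune markers had a median of -0.19 between the clones, although Fcer1g (0.70) and Cd68 (0.30) were higher in clone 2. Tyrobp was 1.82 higher there, but below background. The measured markers were well above background on every array, vehicle included, so they could not exclude a small amount. A difference in interferon signalling between the clones may therefore be considered as a hypothesis; whether it came with the clone or with the culture stays open with 1 array per clone.

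The MRTF-SRF list was lower in both clones than in wild-type cells under TGF-β1. Isolated bright spots on the wild-type array are argued against by a median of -0.47 over 29 members well above background on all 5 arrays, and a brightness-dependent shift by percentile 0 of both clones among matched random lists. Against the vehicle array the clone mean had a median of -0.00465, with 16 of 32 members below 0. The CCG1423 culture had a median of 0.59 against vehicle, which speaks against a chance high level on the TGF-β1 array alone if it received TGF-β1 as its title says, but CCG1423 differs between them too. A weaker MRTF-SRF response in the Tmsb4x-edited clones and a chance high level in the single wild-type TGF-β1 culture could not be told apart. No second wild-type culture had TGF-β1 alone. No clone had vehicle, so a response to TGF-β1 was not measured in the clones, and they may differ from wild type without it. No unedited clone was measured either, so a difference that comes with cloning stays open too.

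A further pattern concerned genes far above background on a single array: 70 with vehicle, 52 with TGF-β1, 64 with CCG1423, and 55 and 84 in the clones. Each was well above background on that array only and at least 2 higher on the log2 scale than on every other array. By that choice, all 52 on the TGF-β1 array counted as higher with TGF-β1, lower with CCG1423 and lower in both clones. Transcription brought on by TGF-β1 in wild-type cells is argued against as the source of the pattern as a whole, because that array held 0.62 times as many such genes as the highest other array; with any gene well above background there alone it held 410, against 380 at most elsewhere. The 19 other probes of these genes that were above background showed a median difference of 0.0195, with 3 at least 2-fold higher on the same array and a median of 0.40 for those of clone 2, so isolated spot signals may account for part of them. Only 1 of those probes bore on the TGF-β1 array, so its 52 genes stay open one by one.

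Probes that matched no gene entered only an alternative: among 9146 unnamed probes well above background on both arrays, 234 (2.56%) were at least 2-fold higher with TGF-β1 than with vehicle and 163 (1.78%) were lower. These shares are close to those of named genes, with 1 probe each, between the clones (307 higher and 236 lower of 12368).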

How the results depend on the processing

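Alternatives that used all probes or only genes well above background on every array compared, and nothing else here, were chosen after the data were seen. No paired analysis was possible because the groups share no more than 1 replicate number.

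TGF-β1 against vehicle gave 1162 genes at 2-fold. This became 567 with normexp, 2584 with no filter on dim probes, 511 with genes well above background on all 5 arrays, 2262 at 1.5-fold, 602 at 3-fold, 345 with limma and the spread of the clones, 622 with measured genes alone and 2570 over all probes. CCG1423 against TGF-β1 alone gave 1826, and in the same order 850, 3275, 1139, 4364, 675 and 279, with 4235 over all probes. The clones gave 313 at 2-fold in both. This became 124 with normexp, 884 with no filter, 100 with genes above background on all 5 arrays, 856 at 1.5-fold, 134 at 3-fold, 132 with measured genes and 707 over all probes, and 1048 to 1117 with either clone alone. The overlap of 360 became 166, 824, 136, 691 and 171 under normexp, no filter, all 5 arrays, 1.5-fold and 3-fold, and 774 over all probes. Its part lower in both clones, 167 genes, became 271 with clone 1 alone and 234 with clone 2 alone. With limma the 32 genes of the knockout became 0 with quantile normalization and 0 with the mean of all probes. These gave 785 and 753 genes at an unadjusted p under 0.05, which a share of 0.05 of unchanged genes would pass. The 32 genes became 76 with normexp, 53 with median scaling and 220 with the deposited table. No filter gave 279, and genes above background on all 5 arrays gave 1. Other fits gave 184 without the trend, 148 with robust moderation, 75 on the 3 arrays compared, 98 at adjusted p 0.1 and 146 over all probes. Thresholds, filters and probe sets change these counts by construction; for the others the cause was not tested. The other alternatives kept each count within 1.5 times.

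The share of higher genes moved too. For CCG1423 it went from 46.3% to 33.5% with the deposited table. It rose to 50.9% with the mean of probes, 51.7% over all probes and 52.3% at 3-fold. For TGF-β1 it went from 60.2% to 73.6% with genes above background on all 5 arrays. For the clones 96 higher and 217 lower genes became 52 and 273 with the deposited table and 25 and 99 with normexp. The higher share there became 55.0% with genes above background on all 5 arrays and 49.3% with the mean of probes. Each clone alone had more higher than lower genes, 642 and 475 in clone 1 and 665 and 383 in clone 2. Of 358 list medians under alternatives, 356 held within the spread of the clones and 1 moved beyond it. That spread was 0.52, the SD over genes of clone 2 minus clone 1. It is larger than many of the medians, so a list could lose its difference and still count as held. The interferon list in the knockout reversed with clone 2 alone, at 1.09, against -1.54 with clone 1 alone. Of 64 list percentiles, 58 held and 6 moved when the random lists were not matched on mean expression. Of 945 values of named genes, 870 held and 75 moved, 49 of these with normexp and 26 with the mean of probes; 0 reversed. Rhox5 passed in 9 of 11 settings and Adm in 8 of 10, whereas Tmsb4x passed in 2 of 11 and Myl9 in 4 of 11. Between 48.2% and 53.8% of probes lay well above background on each array, so dim genes enter by bounds or not at all, and the single arrays limit every other count.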

Other observations

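Comparisons with the vehicle array were made after the results were seen.

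Cells given TGF-β1 and CCG1423 can also be set against vehicle. MRTF-SRF targets then had a median of 0.59, above all matched random lists, with 8 of 33 members at least 2-fold higher, and SMAD targets had a median of 0.50. Set directly against TGF-β1 alone, the MRTF-SRF median was -0.25, so the 0.59 does not show a rise with CCG1423. Melanocyte genes stood at -0.77, with 12 of 27 members at least 2-fold lower, against 5 of 27 with TGF-β1 alone. Cell cycle genes had a median of -0.92 and cholesterol synthesis genes -1.14, with 13 of 29 and 12 of 19 members lower. In 2162 of 13842 genes the difference was 2-fold or more.

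The clones under TGF-β1, set against wild-type cells with vehicle, had SMAD targets at a median of 0.63 (percentile 100) and YAP-TEAD targets at 0.29. The 33 MRTF-SRF targets measured here, 1 more than in the knockout comparison, stood at -0.03 (percentile 30.9) and melanocyte genes at 0.06 (70.3), each near the vehicle level. Cited1, Gsta2 and Tspan10 were among 7 genes lower with TGF-β1 in wild-type cells and higher in both clones than in those cells, against 0.62 for independent lists and a mean of 66.9 in simulations of unchanged arrays. Ddit3, Slc7a11, Gstm1 and Plk2 were among 31 genes lower with TGF-β1 and higher once CCG1423 was added, against 5.06 and 92.5. The simulated noise can be too large, so how much of either set comes from the shared array stays open.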
